A study of Homo sapiens with 12 samples.

How the data were processed

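Gene expression was measured by RNA sequencing in HEK293T cells, a human embryonic kidney cell line that carries the large T antigen of simian virus 40. Per the labels, the cells were kept for 48 h after transfection, in dishes of 100 mm, with a total of 5.4 pmol of plasmid, and libraries were made from 1 ng of RNA. The 12 libraries form 3 groups of 4: cells without plasmid, cells given a plasmid for dCas9-VP160, and cells given dCas9-VP160 with 6 guide RNAs for the CD34 promoter. Each group was assayed in 2 experiments, which the labels describe as separate batches of cells, with 2 technical replicates in each. The labels describe the cells without plasmid once as non-transfected and once as given the transfection reagents alone. No group received a plasmid without dCas9-VP160, so the plasmid and the protein cannot be told apart, and the amount of dCas9-VP160 plasmid in each transfected group is not given in the sources used here.

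The authors deposited a table of raw read counts per gene, with 1 column per library and whole numbers throughout. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.3.7 and aligned with STAR 2.6.0c to hg38, and Picard 2.17.1 and DESeq2 1.16.1 were also used. The program that counted the reads and the release of the gene annotation are not given in the sources used here. The labels name a directional library, whereas the kits they name, SMART-Seq HT and Nextera XT, do not mark the strand, so overlapping sense and antisense genes cannot be told apart and their values are uncertain. Reads of near-identical genes (paralogs, pseudogenes, multigene families and nuclear copies of mitochondrial genes) can likewise be shared between them. A second table that the authors deposited lists 97 genes with the column names of DESeq2. Per the file headers it holds the mean normalised signal over libraries (baseMean), the log2 fold changes between control and each transfected group with their standard errors on the log2 scale, a Wald statistic (a score), and p-values with adjusted p-values. The model behind that deposited table and the way its 97 genes were chosen are not given in the sources used here.

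The count table holds 60604 gene identifiers, of which 41124 matched the gene name reference and 56812 matched GENCODE v29 on GRCh38, the source of gene types and coordinates. The counts of 92 spike-in sequences were kept out of library sizes and tests. Their share was 0.719% (95% exact Clopper-Pearson interval 0.714 to 0.725) and 0.404% (0.400 to 0.407) of counts in replicates 1 and 2 of experiment 1 without plasmid, and at most 0.00818% in every other library. A gene with 0 counts in a library could have been present at up to 0.251 to 0.444 CPM, the level of 3 counts, depending on the library. Intervals and such limits cover counting error only.

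The choices of groups, test, covariates, gene lists, rule for named genes and most alternatives were made before the data were examined. The 2 technical replicates of each treatment in each experiment were summed, which left 6 libraries and n = 2 experiments per group. The experiment number marks a shared batch of cells per the labels, and it entered the model as a block. As a check, the differences between experiments 2 and 1 were compared across 12871 genes, and their correlation between groups was 0.604 to 0.627 in all 3 pairs of groups. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM normalisation, robust quasi-likelihood fit and test), which kept 19662 genes and at least 99.8% of counts in each library. The fit had 2 residual degrees of freedom per gene, a median prior of 24.0 degrees of freedom and a common dispersion of 8.88e-04. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. P-values of this fit rest on how far the differences between groups varied between the 2 experiments, with the spread partly borrowed from other genes. They do not describe independent cell lines. Camera p-values compare genes, and those of fits on 12 libraries or on 1 experiment rest in part or in whole on the spread of technical replicates. Levels are TMM-normalised CPM (counts scaled to a common library total) of the summed libraries, with the SD of the 2 experiments. Log2 fold changes are those of the edgeR fit, and log2 fold changes within an experiment used a prior count of 2. The standard errors (SE) are approximate. Each was derived from the test as the absolute log2 fold change divided by the square root of its F statistic. Whether a response differed between experiments was tested with the interaction term of an edgeR fit on the 12 libraries, whose spread is that of technical replicates.

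The 25 gene lists covered interferon-stimulated genes, cytokines, NF-kB targets, nucleic acid sensors, MHC class I antigen presentation, immediate early genes, p53 targets, the unfolded protein response, the integrated stress response, heat shock, NRF2 and metal response, hypoxia, cholesterol synthesis, the mitotic cell cycle, S phase, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, lysosome and autophagy, TGF-beta and YAP targets, haematopoietic and endothelial markers, neuronal genes, epithelial and kidney genes, and fibroblast and mesenchymal genes. Each list was compared with the remaining genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Members were counted as called over all tested genes and as adjusted over the list alone. Some genes belong to more than 1 list, such as CXCL8 (NF-kB targets and cytokines) and ATF3 (immediate early genes and integrated stress response). Calls of lists that share members are therefore not separate evidence. The genes named are CD34, the 8 largest rises and the 8 largest falls of a comparison (called, with a symbol, a mean CPM of at least 5 and the same direction in both experiments), up to 3 called members of each list with the smallest p-values, and the tested genes within 1 Mb of CD34. The text gives values for part of these genes, and the others are not reported here. Any other gene or family named was chosen after its values were seen, and the text says so.

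The fits were first tested on simulated counts with known changes in the cells with guides, scored in the comparison with dCas9-VP160 alone. The means were pooled over the 3 groups within each experiment, and the library sizes were those of the data. Of 19221 simulated genes tested, edgeR recovered 46.3% of 67 genes changed 1.25-fold, 65.7% of 67 changed 1.5-fold and 78.8% of 66 changed 2-fold, and called 7 unchanged genes. On those counts DESeq2 1.42.0 recovered 29.9%, 47.8% and 62.1% and called 0 unchanged genes. On a separate draw of 12 libraries with the spread of technical replicates, limma-voom recovered 50.7%, 64.2% and 84.8% of the genes. It called 33 unchanged ones among 17399 tested. The interaction test recovered 5.97%, 37.3% and 63.6% among 17801 genes, with 3 unchanged genes called. When the 27 tested members of the unfolded protein response list were all raised 1.25-fold, camera gave an adjusted p of 3.31e-159 with the preset and 0.0503 with an estimated correlation, and called no other list. The estimated correlation thus left even this rise uncalled, on a fit with 2 residual degrees of freedom. A list not called under that setting is therefore not evidence of no change. The simulated genes varied independently of each other, so these draws cannot show how either setting treats correlated genes.

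The alternatives were DESeq2 size factors, DESeq2's Wald test, no filter or a filter at a mean CPM of 1, and no experiment term. Limma-voom was run on the 12 libraries, with the unit of treatment and experiment as a random effect. The technical replicates were also taken as separate samples or with a block for each experiment and replicate number. For the lists, fry and an estimated correlation were used. Further alternatives were each experiment alone, only the 2 groups compared, stricter thresholds, and each of the 12 libraries left out in turn. Those on 12 libraries, on fewer libraries or with another filter also changed the genes that entered the test. Chosen after seeing the data were replicate 1 or replicate 2 alone, the experiment 1 libraries without plasmid left out, the mitochondrial genes left out, and an estimated correlation on the 12 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.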

Results

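RNA was sequenced from HEK293T cells in 3 conditions. The cells received no plasmid, dCas9-VP160 alone, or dCas9-VP160 with 6 guide RNAs for the CD34 promoter. The protein dCas9-VP160 is a Cas9 without nuclease activity joined to a viral transcriptional activator. The 4 libraries of each condition came from 2 experiments on separate batches of cells. The 12 libraries held 6750035 to 11932244 gene counts and detected 26115 to 28418 genes. After the technical replicates were summed, the 6 libraries held 16359839 to 20968535 counts of tested genes. Levels are normalised read counts scaled to a common library total (CPM), and errors are the SD of 2 experiments or the approximate SE derived from the edgeR test. The comparisons address how strongly the guides raised their target, which other genes differed once the guides were added, and which genes differed in cells that received dCas9-VP160 without guides.

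CD34, a surface glycoprotein of haematopoietic progenitor and endothelial cells, was close to undetected without guides and abundant with them. Its level was 2.06 ± 6.9e-04 CPM without plasmid, 0.887 ± 0.0171 with dCas9-VP160 alone and 99.3 ± 4.15 with the guides (SD, n = 2 experiments). The gene (ENSG00000174059, chromosome 1, 207880972 to 207911402, minus strand, GRCh38) had 942 and 906 counts in replicates 1 and 2 of experiment 1 with guides, and 887 and 664 in those of experiment 2. The libraries with dCas9-VP160 alone had 8, 7, 9 and 10 counts in the same order, and those without plasmid had 13, 28, 14 and 26. Adding the guides raised CD34 by 6.79 on the log2 scale, or 110.7-fold (SE 0.12, adjusted p = 8.68e-25), with log2 fold changes of 6.70 and 6.58 in experiments 1 and 2. Against cells without plasmid the rise was 5.59, or 48.1-fold (SE 0.10, adjusted p = 1.13e-24). With dCas9-VP160 alone CD34 was lower than without plasmid by a log2 fold change of -1.20 (SE 0.26, adjusted p = 4.17e-04). From the replicate 1 libraries alone, that value was -0.83 (adjusted p = 0.109), and over 29 alternatives its adjusted p ranged from 6.62e-05 to 0.109.

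**Figure D1:**
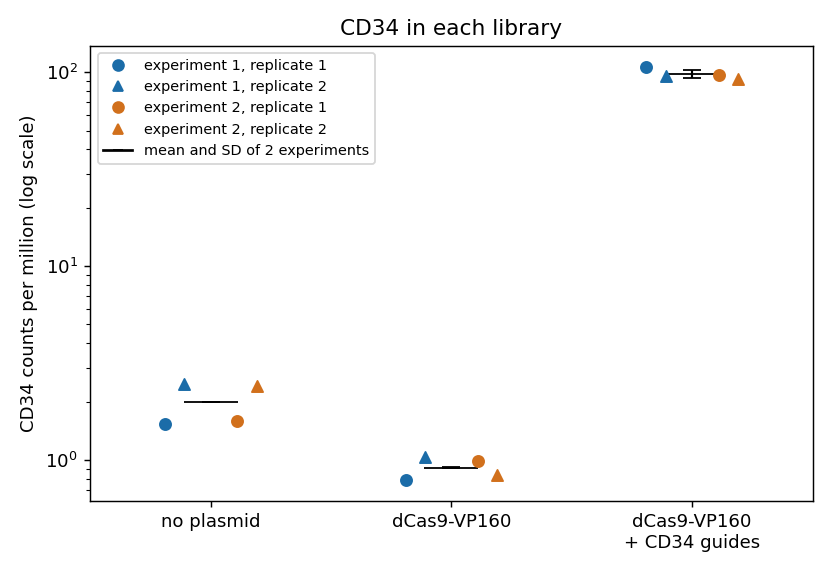
CD34 level in CPM (log scale) in each of the 12 libraries, by condition, with circles for replicate 1, triangles for replicate 2, and lines for the mean and SD of 2 experiments. The libraries with guides lie between 92.1 and 106.8, those without plasmid between 1.53 and 2.47, and those with dCas9-VP160 alone between 0.79 and 1.04.

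In cells that received dCas9-VP160 without guides, genes of the integrated stress response, NF-kB targets and cytokine genes were higher than without plasmid, and mitochondrially encoded and mesenchymal genes were lower. With an estimated correlation between genes none of these 5 lists was called (adjusted p = 0.0516 to 0.141). SLC3A2, the shared chain of several amino acid transporters, rose from 168.5 ± 6.52 to 725.7 ± 34.6 CPM (SD, n = 2; log2 fold change 2.11, SE 0.04, adjusted p = 5.47e-25). TNFRSF9, a co-stimulatory receptor of the tumour necrosis factor family, rose from 6.4 ± 0.0421 to 63.4 ± 6.50 (3.30, SE 0.09, adjusted p = 7.71e-21). GPC3, a cell-surface heparan sulfate proteoglycan, fell from 97 ± 3.70 to 21.5 ± 0.617 (-2.17, SE 0.06, adjusted p = 6.16e-20). SLIT2, a secreted guidance protein, fell from 462 ± 42.5 to 133.9 ± 10.8 (-1.79, SE 0.04, adjusted p = 1.10e-22).

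Of 19662 genes tested, 5234 were higher and 4836 lower with dCas9-VP160, 51.2% in all, with a median absolute log2 fold change of 0.43 among them. An absolute log2 fold change of at least 1 was reached by 868 of the higher and 605 of the lower genes. The other large rises were those of DMRT1, a transcription factor of the testis (4.17, SE 0.18), RELB, a subunit of NF-kB (3.26, SE 0.11), and PLA2G4C, a phospholipase (3.23, SE 0.10). They were followed by CYP4F3, a leukotriene hydroxylase (3.0, SE 0.23), and ANKRD1, an ankyrin repeat protein of stressed muscle (2.92, SE 0.11). DNAH17, a dynein heavy chain of cilia, and its antisense gene DNAH17-AS1 also rose (3.03, SE 0.08, and 4.31, SE 0.24), but reads of the overlapping pair cannot be told apart. The other large falls were those of PCK1, an enzyme of gluconeogenesis (-2.07, SE 0.12), IGFBP5, a binding protein of insulin-like growth factors (-1.92, SE 0.12), MMP2, a gelatinase (-1.76, SE 0.07), NREP (-1.75, SE 0.06), the antisense gene KLRK1-AS1 (-1.77, SE 0.08) and the histone gene H3Y1 (-1.75, SE 0.10), whose reads can be shared with related genes. All of these had adjusted p-values of 2.97e-11 or less.

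**Figure D2:**
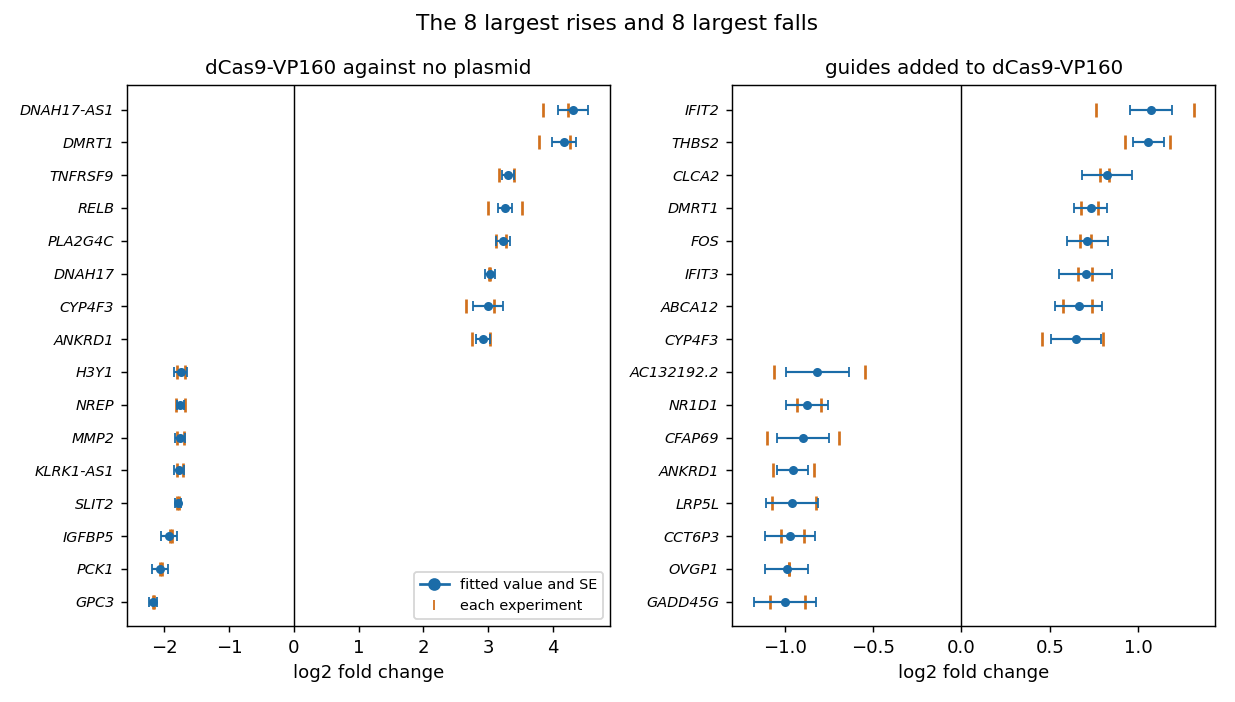
Log2 fold changes of the 8 largest rises and 8 largest falls with dCas9-VP160 against no plasmid and on adding guides to dCas9-VP160, among genes with a mean CPM of at least 5 and with CD34 left out. Points and bars are the fitted value and its SE, and ticks are the values of each experiment, computed with a prior count of 2. Values span -2.17 for GPC3 to 4.31 for DNAH17-AS1 in the left panel and -1.0 for GADD45G to 1.07 for IFIT2 in the right one.

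The integrated stress response list holds genes that the transcription factor ATF4 controls. Of its 36 tested members 33 were higher, 1 was lower and 2 were not called with dCas9-VP160 against no plasmid, with the same counts adjusted over the list alone. The median log2 fold change was 0.98 (camera adjusted p = 9.65e-78, and adjusted p = 0.0516 with an estimated correlation). PPP1R15A, which directs a phosphatase to the initiation factor eIF2-alpha, rose from 64.3 ± 4.14 to 269.9 ± 24.4 CPM (SD, n = 2; log2 fold change 2.07, SE 0.04, adjusted p = 6.82e-23). DDIT3, the stress-induced transcription factor CHOP, rose from 31.9 ± 1.75 to 141 ± 7.39 (2.15, SE 0.05, adjusted p = 3.20e-21). Of 24 tested NF-kB targets 19 were higher and 2 lower, with the same counts adjusted over the list alone (median 0.86, camera adjusted p = 4.09e-15, and adjusted p = 0.108 with an estimated correlation). Among them NFKB2, a precursor of an NF-kB subunit, rose from 8.23 ± 0.357 to 49.4 ± 6.13 (2.58, SE 0.09, adjusted p = 6.07e-19) and TNFAIP3, a ubiquitin-editing inhibitor of NF-kB, by 1.55 (SE 0.09). Of 16 tested interferon, chemokine and cytokine genes 11 were higher and 1 lower, and 13 and 1 adjusted over the list alone (median 1.45, camera adjusted p = 9.13e-07, and adjusted p = 0.108 with an estimated correlation). The cytokine IL32 rose from 22.8 ± 1.89 to 105.9 ± 7.18 (2.21, SE 0.06, adjusted p = 7.71e-21), the neutrophil chemokine CXCL8 by 2.47 (SE 0.16) and the macrophage growth factor CSF1 by 0.93 (SE 0.07).

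Genes of the cell's stress and damage programmes were also higher with dCas9-VP160 than without plasmid. Among 30 tested p53 targets 20 were higher and 3 lower, with the same counts adjusted over the list alone (median 0.37, camera adjusted p = 5.58e-12, and adjusted p = 0.141 with an estimated correlation). AEN, an apoptosis-linked nuclease (1.19), TIGAR, a regulator of glycolysis (1.31), and GADD45A, a growth arrest gene (1.1), rose. The list shares GDF15 and SESN2 with the integrated stress response list, and the activity of p53 itself was not measured. Among 22 NRF2 and metal response genes 13 were higher and 1 lower, likewise adjusted over the list alone (median 0.35, camera adjusted p = 9.30e-09, and adjusted p = 0.108 with an estimated correlation). The cystine transporter SLC7A11 (2.55), the autophagy receptor SQSTM1 (1.22) and the ferritin light chain FTL (1.08) rose. SLC7A11 is also a member of the integrated stress response list, and SQSTM1 of the lysosome and autophagy list. Among 33 immediate early and AP-1 genes 18 were higher and 4 lower, likewise adjusted over the list alone (median 0.70, camera adjusted p = 4.07e-07, and adjusted p = 0.237 with an estimated correlation). The transcription factors JUNB (1.56) and ATF3 (1.19) and the phosphatase gene DUSP1 (0.83) rose. Among 33 lysosome and autophagy genes 20 were higher and 6 lower, likewise adjusted over the list alone (median 0.24, camera adjusted p = 9.48e-07, and adjusted p = 0.108 with an estimated correlation). The membrane glycoprotein GPNMB rose from 8.59 ± 0.584 to 50.1 ± 5.0e-04 CPM (SD, n = 2; 2.54, SE 0.08). Among 27 unfolded protein response genes 19 were higher and 3 lower, likewise adjusted over the list alone (median 0.20, camera adjusted p = 1.68e-05, and adjusted p = 0.198 with an estimated correlation). XBP1, a transcription factor (1.12), and the chaperones CANX (0.68) and HSPA5 (0.58) rose. Among 26 heat shock genes 12 were higher and 4 lower, and 12 and 5 adjusted over the list alone (median 0.07, camera adjusted p = 0.00902, and adjusted p = 0.198 with an estimated correlation). The chaperones HSPB8 (1.37) and HSPH1 (0.95) rose. Without a filter on low counts the heat shock list was not called (camera adjusted p = 0.0533).

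Growth, antigen presentation and matrix genes differed as well between dCas9-VP160 and no plasmid. Of 38 ribosome biogenesis and MYC target genes 31 were higher and 2 lower, likewise adjusted over the list alone (median 0.49, camera adjusted p = 3.50e-15, and adjusted p = 0.108 with an estimated correlation). The nucleolar factors RRP12 (1.41), DDX21 (1.01) and PES1 (0.74) rose. Of 46 S phase genes 31 were higher and 4 lower, and 32 and 4 adjusted over the list alone (median 0.20, camera adjusted p = 1.24e-07, and adjusted p = 0.108 with an estimated correlation). CDC6, which licenses replication origins, rose by 0.88. Of 36 mitotic genes 5 were higher and 24 lower, and 6 and 24 adjusted over the list alone (median -0.25, camera adjusted p = 9.69e-06, and adjusted p = 0.198 with an estimated correlation). The mitotic kinesin KIF20A (-0.54), the ubiquitin-conjugating enzyme UBE2C (-0.51) and the topoisomerase TOP2A (-0.40) fell. Of 19 MHC class I antigen presentation genes 11 were higher and 0 lower, likewise adjusted over the list alone (median 0.23, camera adjusted p = 7.88e-04, and adjusted p = 0.239 with an estimated correlation). The peptide transporter TAP1 (1.38), the light chain B2M (0.39) and HLA-B (0.53), whose reads can be shared with other HLA genes, rose. Of 16 fibroblast and mesenchymal genes 1 was higher and 10 lower, likewise adjusted over the list alone (median -0.31, camera adjusted p = 4.27e-09, and adjusted p = 0.108 with an estimated correlation). Fibronectin, FN1, fell from 558 ± 87.3 to 221 ± 28.1 CPM (SD, n = 2; -1.33, SE 0.04, adjusted p = 3.36e-20), and the collagen gene COL3A1 (-1.69) and the matrix glycoprotein gene SPARC (-0.68) also fell.

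The mitochondrially encoded genes took a smaller share of the libraries with dCas9-VP160. Their share of counts was 8.55 ± 0.0021% without plasmid and 5.44 ± 0.229% with dCas9-VP160 (SD, n = 2). Of the 15 genes, whose reads can be shared with nuclear copies, 0 were higher and 14 lower, likewise adjusted over the list alone (median -0.74, camera adjusted p = 5.54e-30, and adjusted p = 0.141 with an estimated correlation). MT-CYB, a subunit of complex III, fell by 0.94 (SE 0.03, adjusted p = 3.85e-19), and MT-CO3, a subunit of complex IV, fell by 0.89 (SE 0.03).

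**Figure D3:**
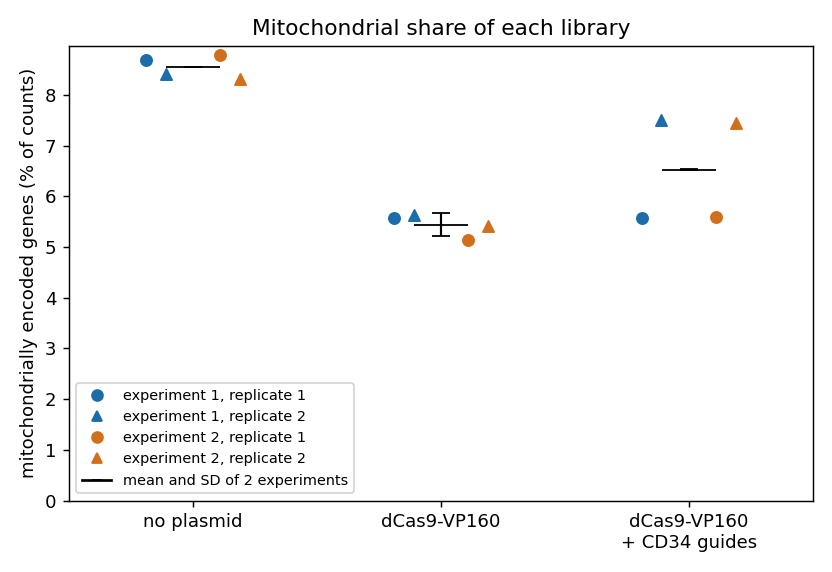
Share of gene counts (%) in mitochondrially encoded genes in each of the 12 libraries, by condition, with circles for replicate 1, triangles for replicate 2, and lines for the mean and SD of 2 experiments. With guides the replicate 1 libraries hold 5.57 and 5.59% and the replicate 2 libraries 7.50 and 7.44%.

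The remaining lists held called members on both sides with dCas9-VP160 against no plasmid, and none was called by camera. Fry did call the nucleic acid sensors (fry adjusted p = 0.0223), hypoxia (0.00610), cholesterol (0.0194) and neuronal genes (0.00512). Among 45 interferon-stimulated genes 17 were higher and 14 lower, and 18 and 14 adjusted over the list alone (adjusted p = 0.886). IFIT2, a translation inhibitor (2.52), and the ubiquitin-like ISG15 (1.70) rose, and LGALS3BP, a galectin-binding glycoprotein (-0.51), fell. Counts of higher and lower genes were 8 and 2 of 15 nucleic acid sensors (adjusted p = 0.133), with the RNA sensor TLR3 higher (1.58) and the adaptor MAVS lower (-0.39). They were 16 and 7 of 35 hypoxia genes (adjusted p = 0.133) and 7 and 18 of 30 cholesterol synthesis and uptake genes (adjusted p = 0.0874). They were 29 and 15 of 64 ribosomal protein genes (adjusted p = 0.463) and 14 and 22 of 57 nuclear oxidative phosphorylation genes (adjusted p = 0.470). For the sensors and these 4 lists the counts were the same adjusted over the list alone. Ribosomal protein genes had 10 higher and 23 lower from the replicate 1 libraries alone (camera adjusted p = 0.104). From the replicate 2 libraries alone they had 30 and 6 (0.00175). Oxidative phosphorylation genes had 10 and 28 (camera adjusted p = 0.00302) and 16 and 10 (0.298) in the same order. The direction of these 2 lists thus depended on the technical replicate. The angiogenic factor VEGFA rose (0.84), the fatty acid synthase gene FASN fell (-0.69) while the sterol enzyme HSD17B7 rose (0.90), and RPL3 fell while RPL4 rose (-0.50 and 0.38), with reads that can be shared with their pseudogenes. Counts were 9 and 8 of 28 TGF-beta and YAP targets, or 9 and 9 adjusted over the list alone (adjusted p = 0.948), and 6 and 7 of 18 epithelial and kidney genes, or 7 and 7 adjusted over the list alone (adjusted p = 0.485). They were 4 and 5 of 15 haematopoietic and endothelial markers (adjusted p = 0.792) and 10 and 4 of 18 neuronal genes (adjusted p = 0.112), likewise adjusted over the list alone. The stem cell factor receptor KIT was lower (-0.85), and the endothelial adhesion gene ESAM (1.98) and the transcription factor GATA2 (0.55) were higher. The synaptic gene SNAP25 was higher (2.2) and the microtubule protein gene MAP2 lower (-0.85). The median, the mean and the direction of the test differed in sign for the interferon-stimulated genes (0.019, 0.163, down), the TGF-beta and YAP targets (-0.022, 0.160, down) and the haematopoietic markers (0.0042, 0.034, down).

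**Figure D4:**
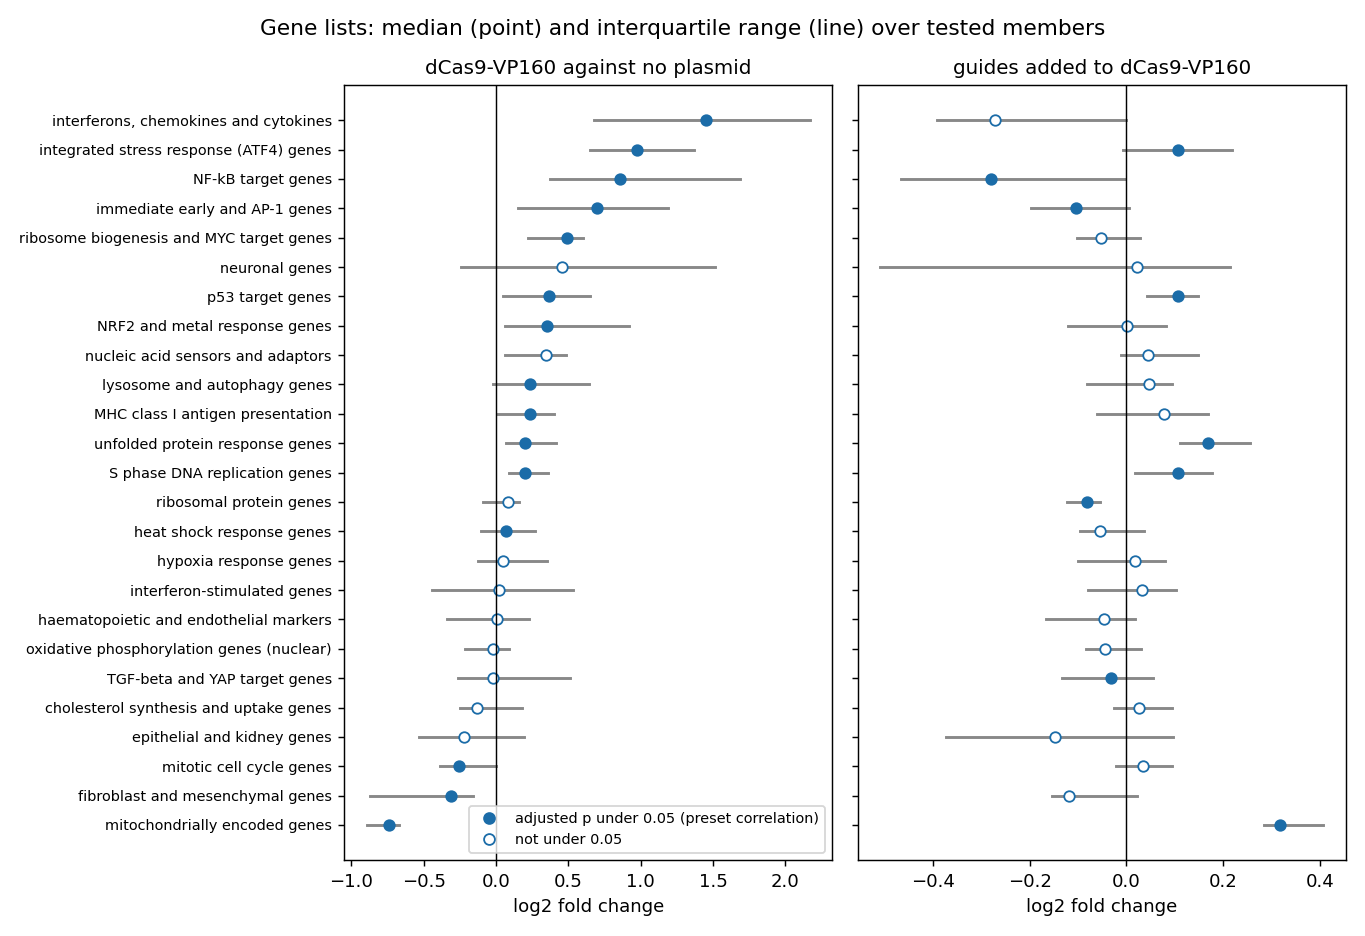
Median (point) and interquartile range (line) of log2 fold changes over the tested members of each of the 25 gene lists, with dCas9-VP160 against no plasmid and on adding guides to dCas9-VP160. Filled points are lists called by camera with the preset correlation; the left medians run from -0.74 for mitochondrially encoded genes to 1.45 for cytokines, and the right ones from -0.28 for NF-kB targets to 0.32 for mitochondrially encoded genes.

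When the guides were added to dCas9-VP160, the changes beyond CD34 were mostly small: unfolded protein response and S phase genes were higher and NF-kB genes were lower. With an estimated correlation none of these 3 lists was called (adjusted p = 0.164 for each). XBP1, the transcription factor of the unfolded protein response, rose from 448 ± 12.2 to 575 ± 13.1 CPM (SD, n = 2; log2 fold change 0.36, SE 0.03, adjusted p = 1.50e-07). THBS2, a matrix glycoprotein that limits vessel growth, rose 2.08-fold, from 20.4 ± 3.0 to 42.2 ± 0.966 (1.06, SE 0.09, adjusted p = 3.33e-08). NFKB2 fell from 49.4 ± 6.13 to 28.5 ± 1.97 (-0.79, SE 0.07, adjusted p = 7.01e-08), and ANKRD1 from 31.9 ± 2.08 to 16.4 ± 0.810 (-0.96, SE 0.09, adjusted p = 1.05e-07). Both lay lower still without plasmid, at 8.23 and 4.22 CPM.

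With the guides 817 genes were higher and 670 lower, 7.56% of 19662 tested, with a median absolute log2 fold change of 0.25 among them. An absolute log2 fold change of at least 1 was reached by 19 higher and 57 lower genes, CD34 included. Among genes with a symbol and a mean CPM of at least 5, the only such rises were CD34, IFIT2 and THBS2. The largest fall there was that of GADD45G (-1.0). Most of the 19 and 57 genes therefore had lower levels or no symbol. Further rises were those of CLCA2, a p53-responsive regulator of chloride currents (0.82, SE 0.14, adjusted p = 3.93e-04), and DMRT1 (0.73, SE 0.09, adjusted p = 1.29e-05). They included FOS, an AP-1 transcription factor (0.71, SE 0.12, adjusted p = 2.32e-04), and ABCA12, a lipid transporter (0.66, SE 0.13, adjusted p = 0.00201). Further falls were those of GADD45G, a growth arrest gene (-1.0, SE 0.18, adjusted p = 5.84e-04), OVGP1, an oviduct glycoprotein (-0.99, SE 0.12, adjusted p = 5.78e-06), and NR1D1, a repressor of the circadian clock (-0.87, SE 0.12, adjusted p = 2.45e-05). Others were LRP5L (-0.96), CFAP69 (-0.90), AC132192.2 (-0.82) and the pseudogene CCT6P3 (-0.97), whose reads can be shared with its parent gene. CYP4F3 was higher by 0.65 (adjusted p = 0.00427), but without replicate 1 of experiment 1 with guides the value was 0.48 (adjusted p = 0.0869).

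Among 27 unfolded protein response genes 14 rose and 0 fell when guides were added, and 18 and 0 adjusted over the list alone (median 0.17, camera adjusted p = 2.99e-19, and adjusted p = 0.164 with an estimated correlation). The chaperone CANX rose by 0.29 (SE 0.03, adjusted p = 7.30e-07) and SEL1L, part of the machinery that degrades misfolded proteins, by 0.37 (SE 0.04, adjusted p = 2.45e-06). Of 46 S phase genes 18 were higher and 1 lower, and 25 and 2 adjusted over the list alone (median 0.11, camera adjusted p = 5.43e-12, and adjusted p = 0.164 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase (0.29), the ubiquitin ligase gene DTL (0.31) and CDC6 (0.30) rose. Of 36 integrated stress response genes 11 were higher and 2 lower, and 16 and 4 adjusted over the list alone (median 0.11, camera adjusted p = 8.44e-08, and adjusted p = 0.164 with an estimated correlation). The stress regulator NUPR1 (0.61) and the tRNA synthetase genes AARS1 (0.29) and SARS1 (0.26) rose. Of 30 p53 targets 9 were higher and 1 lower, and 16 and 3 adjusted over the list alone (median 0.11, camera adjusted p = 2.48e-06, and adjusted p = 0.328 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.0963). TP53I3, an oxidoreductase (0.47), and FDXR, the reductase of ferredoxin (0.26), rose.

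NF-kB targets went the other way: of 24 tested, 0 rose and 9 fell with guides, and 2 and 15 adjusted over the list alone (median -0.28, camera adjusted p = 1.11e-10, and adjusted p = 0.164 with an estimated correlation). NFKB1, the precursor of the p50 subunit, fell by 0.45 (SE 0.06, adjusted p = 9.99e-06) and TNFAIP3 fell by 0.59 (SE 0.08, adjusted p = 3.51e-05). Of 64 ribosomal protein genes, whose reads can be shared with pseudogenes, 0 were higher and 11 lower, and 0 and 24 adjusted over the list alone (median -0.08, camera adjusted p = 1.25e-09, and adjusted p = 0.463 with an estimated correlation). The list was not called from experiment 2 alone (camera adjusted p = 0.293). Of 28 TGF-beta and YAP targets 0 were higher and 4 lower, likewise adjusted over the list alone (median -0.03, camera adjusted p = 0.0172, and adjusted p = 0.328 with an estimated correlation). The matrix protein gene CCN2 (-0.40) and AMOTL2, an angiomotin gene (-0.33), fell. Of 33 immediate early genes 1, FOS, was higher and 5 lower, and 2 and 6 adjusted over the list alone (median -0.10, camera adjusted p = 0.0225, and adjusted p = 0.463 with an estimated correlation). The cyclin gene CCNL1 fell by 0.31. Without replicate 1 of experiment 1 with dCas9-VP160 alone, camera gave an adjusted p of 0.0782 for both of these lists, and without replicate 1 of experiment 2 of that group 0.0853 for the immediate early and AP-1 genes. The TGF-beta and YAP list was also not called from experiment 2 alone (0.187), the replicate 2 libraries alone (0.0841) or without a filter (0.153). The immediate early list was not called from experiment 1 alone (0.352) or the replicate 2 libraries alone (0.197).

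The mitochondrially encoded genes and the interferon-induced genes IFIT2 and IFIT3 differed between the technical replicates with guides. The mitochondrial share was 5.57 and 5.59% in the replicate 1 libraries and 7.50 and 7.44% in the replicate 2 libraries, against 5.14 to 5.63% with dCas9-VP160 alone. Of the 15 genes, whose reads can be shared with nuclear copies, 12 were higher and 0 lower with the summed libraries, and 13 and 0 adjusted over the list alone (median 0.32, camera adjusted p = 3.17e-41, and adjusted p = 0.185 with an estimated correlation). From the replicate 1 libraries alone the median was 0.05, with 0 genes higher and 1 lower (camera adjusted p = 0.259), and from the replicate 2 libraries alone it was 0.53, with 13 higher and 0 lower. IFIT2 was higher by 1.07 (SE 0.12, adjusted p = 1.99e-06) and IFIT3 by 0.70 (SE 0.15, adjusted p = 0.00358) in the summed libraries. From the replicate 1 libraries alone these values were 1.69 and 1.19, and from the replicate 2 libraries alone 0.08 (adjusted p = 0.867) and 0.04 (adjusted p = 0.953). Without replicate 1 of experiment 1 with guides, IFIT2 was at 0.89 (adjusted p = 0.131) and IFIT3 at 0.50 (adjusted p = 0.156), and without replicate 1 of experiment 2 with guides they were at 0.62 and 0.50 (adjusted p = 0.0749 for IFIT3). Of the 45 interferon-stimulated genes, 3 were higher and 0 lower, likewise adjusted over the list alone (camera adjusted p = 0.199).

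The remaining lists were not called on adding the guides. Counts of higher and lower genes were 0 and 2 of 16 cytokine genes, or 1 and 4 adjusted over the list alone (adjusted p = 0.0705), and 1 and 1 of 15 nucleic acid sensors, or 4 and 1 (adjusted p = 0.187). They were 2 and 0 of 19 antigen presentation genes, or 3 and 1 (adjusted p = 0.0847), and 2 and 2 of 26 heat shock genes, the same adjusted over the list alone (adjusted p = 0.239). Counts were 1 and 2 of 22 NRF2 and metal response genes, or 2 and 2 adjusted over the list alone (adjusted p = 0.818), and 2 and 1 of 35 hypoxia genes, or 4 and 1 (adjusted p = 0.397). They were 4 and 0 of 30 cholesterol genes, the same adjusted over the list alone (adjusted p = 0.0585), and 4 and 1 of 36 mitotic genes, or 5 and 1 (adjusted p = 0.0585). The sterol enzymes ACAT2 (0.25) and EBP (0.24) rose. Counts were 1 and 2 of 38 ribosome biogenesis genes, or 1 and 3 adjusted over the list alone (adjusted p = 0.0585). Oxidative phosphorylation genes had 1 and 2 of 57, the same adjusted over the list alone (adjusted p = 0.0585), and lysosome genes 5 and 2 of 33, or 7 and 4 (adjusted p = 0.0847). GPNMB rose from 50.1 ± 5.0e-04 to 75.1 ± 3.65 CPM (SD, n = 2; 0.58, SE 0.06, adjusted p = 7.30e-07), and the lysosomal channel gene MCOLN1 fell (-0.43). Of 18 neuronal genes 4 were higher and 2 lower, or 5 and 2 adjusted over the list alone (adjusted p = 0.645). Counts were 0 and 2 of 18 epithelial genes, the same adjusted over the list alone (adjusted p = 0.306), and 1 and 2 of 16 mesenchymal genes, or 1 and 3 (adjusted p = 0.0951). The 2 neuronal genes that fell were the stathmin gene STMN4 (-1.55) and SNAP25 (-0.81), and ENO2 rose by 0.24 but was not called without replicate 1 of experiment 1 with guides (0.20). The haematopoietic and endothelial markers, genes of cells that normally carry CD34, had 0 higher and 0 lower of 15 by edgeR, likewise adjusted over the list alone (camera adjusted p = 0.594). At an unadjusted p under 0.05 there was 1, GATA2 (-0.16, named after its values were seen), and DESeq2 called 0. The median, the mean and the direction of the test differed in sign for NRF2 and metal response genes (0.0012, -0.070, down), hypoxia genes (0.018, -0.021, up) and neuronal genes (0.023, -0.166, up).

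Of 34 annotated genes within 1 Mb of CD34, 10 were expressed well enough to be tested, and 1 of them was called when guides were added. CD46, a complement regulator 85.5 kb from CD34, rose from 116.5 ± 8.51 to 142.6 ± 6.56 CPM (SD, n = 2; log2 fold change 0.29, SE 0.05, adjusted p = 1.21e-04), and stood at 151 ± 15.5 without plasmid. The complement regulator CD55 (-0.10), the semaphorin receptor gene PLXNA2 (-0.17), the deubiquitinase gene YOD1 (0.03) and the kinase gene PFKFB2 (-0.08) were not called. The complement receptor gene CR2 was also not called (0.47, adjusted p = 0.259), but without replicate 1 of experiment 1 with dCas9-VP160 alone it was (0.97, adjusted p = 0.0312). FCMR (0.60), C1orf116 (0.37), CR1L (-0.47) and MIR29B2CHG (-0.07) had at most 1.70 CPM in either group and were not called.

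The counts of genes changed by the guides depended on the method and on single libraries. DESeq2 called 270 higher and 90 lower genes, 75.0% of them higher against 54.9% by edgeR. It gave no adjusted p to 51 of the 817 genes called higher by edgeR and to 149 of the 670 called lower. The 2 shares therefore do not cover the same genes. Without the experiment term edgeR called 1 and 0, with 1465 genes at an unadjusted p under 0.05. Without replicate 2 of experiment 2 without plasmid the counts were 420 and 303, and without replicate 1 of experiment 1 with guides they were 501 and 400. Of the genes named above, the replicate 2 libraries alone did not call FOS (0.49), CYP4F3 (0.11), CFAP69 (-0.28), AC132192.2 (-0.63), TP53I3 (0.30), FDXR (0.13), CCN2 (-0.19), AMOTL2 (-0.30), CCNL1 (-0.23), EBP (0.18), MCOLN1 (-0.40) and ENO2 (0.14), nor IFIT2 and IFIT3. The replicate 1 libraries alone did not call CLCA2 (0.59) and ABCA12 (0.40). Since the libraries with dCas9-VP160 alone enter both comparisons with opposite signs, a chance value in them appears as a rise in one and a fall in the other.

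Cells with dCas9-VP160 and guides differed from cells without plasmid in 5245 higher and 5102 lower genes of 19662, 52.6%, and 806 and 761 of them had an absolute log2 fold change of at least 1. Of 36 integrated stress response genes 33 were higher and 2 lower, likewise adjusted over the list alone (median 1.02, camera adjusted p = 7.97e-84, and adjusted p = 0.0478 with an estimated correlation). DDIT3 rose from 31.9 ± 1.75 to 159 ± 0.868 CPM (SD, n = 2; log2 fold change 2.32, SE 0.05, adjusted p = 4.22e-22) and SLC3A2 by 2.14 (SE 0.04, adjusted p = 3.91e-25). Among genes with a mean CPM of at least 5, the largest rises after CD34 were DMRT1 (4.90), DNAH17-AS1 (4.24, overlapping DNAH17), CYP4F3 (3.65), IFIT2 (3.6) and THBS2 (3.4). IFIT2 was at 4.43 from the replicate 1 and 2.54 from the replicate 2 libraries alone. The largest falls among the same genes were IGFBP5 (-2.44), GPC3 (-2.35), PCK1 (-2.33) and KLRK1-AS1 (-2.11, an antisense gene).

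The other lists called against cells without plasmid were higher for p53 targets (22 of 30 higher and 2 lower, median 0.46, camera adjusted p = 7.42e-16), S phase genes (38 and 2 of 46, 0.32, 1.75e-13) and the unfolded protein response (20 and 2 of 27, 0.33, 1.15e-12). They were also higher for ribosome biogenesis (29 and 3 of 38, 0.38, 4.04e-11), NRF2 targets (12 and 2 of 22, 0.34, 1.34e-07), lysosome genes (23 and 6 of 33, 0.28, 2.17e-07) and NF-kB targets (17 and 1 of 24, 0.51, 3.63e-07). Cytokines (12 and 1 of 16, 1.17, 1.18e-04), immediate early genes (14 and 5 of 33, 0.45, 1.46e-04) and antigen presentation genes (12 and 1 of 19, 0.34, 1.52e-04) were also higher. Lower lists were the mesenchymal genes (2 and 11 of 16, -0.42, 1.05e-09), the mitochondrially encoded genes (1 and 13 of 15, -0.43, 1.53e-09) and the mitotic genes (6 and 22 of 36, -0.21, 7.38e-04). Adjusted over the list alone the counts differed for the unfolded protein response (22 and 2), ribosome biogenesis (30 and 3), NRF2 targets (13 and 2), mesenchymal genes (2 and 12) and mitotic genes (6 and 23). None of these was called with an estimated correlation, with adjusted p-values of 0.103 or more, and the mitochondrial list was not called from the replicate 2 libraries alone (camera adjusted p = 0.191). TP53I3 rose from 11.7 ± 0.332 to 58.5 ± 4.26 CPM (2.33, SE 0.08, adjusted p = 2.65e-18) and XBP1 from 206 ± 2.13 to 575 ± 13.1 (1.49, SE 0.04, adjusted p = 5.46e-22). RELB rose from 3.9 ± 1.37 to 24.9 ± 1.6 (2.67, SE 0.12, adjusted p = 5.95e-16), and FN1 fell from 558 ± 87.3 to 200.5 ± 18.0 (-1.47, SE 0.04, adjusted p = 3.38e-21; SD, n = 2). The lists not called were heat shock (11 and 6, camera adjusted p = 0.0524), nucleic acid sensors (8 and 1, 0.0613), hypoxia (16 and 9, 0.0896), neuronal (9 and 5, 0.0896) and oxidative phosphorylation (13 and 24, 0.158). Also not called were ribosomal proteins (18 and 24, 0.215), epithelial (4 and 7, 0.312), cholesterol (7 and 15, 0.345), TGF-beta and YAP (8 and 11, 0.345), haematopoietic (3 and 4, 0.618) and interferon-stimulated genes (16 and 14, 0.765). Fry did call the heat shock (fry adjusted p = 0.00915), nucleic acid sensor (0.01355), hypoxia (0.00489) and neuronal (0.00432) lists. It also called the epithelial (0.0448), TGF-beta and YAP (0.0448) and interferon-stimulated (0.0231) lists. The median, the mean and the direction of the test differed in sign for interferon-stimulated genes (-0.036, 0.203, up), ribosomal protein genes (0.0057, -0.041, down) and TGF-beta and YAP targets (-0.065, 0.078, down). Ribosomal protein genes had 4 higher and 28 lower from the replicate 1 libraries alone, and 21 and 10 from the replicate 2 libraries alone. Oxidative phosphorylation genes had 12 and 29, and 11 and 13, in the same order.

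The difference between the 2 batches of cells was tested with a fit that recovered 37.3% of simulated 1.5-fold and 63.6% of simulated 2-fold differences. Of 17975 genes tested with edgeR, 0 differed between experiments in the response to adding guides, 2 in the response to dCas9-VP160 alone and 0 in the response to both. At an unadjusted p under 0.05 there were 716, 926 and 689 genes, and DESeq2 called 0 in each of the 3 comparisons. The spread in this test is that of technical replicates.

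The authors' deposited table lists 97 genes with values against control cells, 77 higher and 20 lower in both transfected groups. In the authors' deposited table the absolute log2 fold changes ran from 1.17 to 6.15 for dCas9-VP160 alone and from 1.19 to 5.03 with guides, and the largest adjusted p-values were 0.0475 and 0.0468. Its statistic equals the distance of the absolute log2 fold change from 1 divided by the standard error, so the authors' deposited table holds a test against a log2 fold change of 1. All 97 genes were called here in both comparisons, with the sign given in the authors' deposited table and an absolute log2 fold change of at least 1. Across these genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson correlation of 0.9999, and the largest differences were 0.12 and 0.18. With DESeq2 on the 12 libraries and the same threshold, 134 genes passed for dCas9-VP160 alone, 160 with guides and 96 for both, of which 83 are in the authors' deposited table. The 25 lists hold 32 of the 97 genes.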

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

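Chosen only after the result was seen was the fit without the experiment 1 libraries without plasmid, and RCC2 and RPL37A are named after their values were seen. In each group of 4 libraries the highest or lowest value was compared with the other 3 by Dixon's test. Of 15 library measures (such as depth or the mitochondrial share in a group) 0 held a library far from the others, and of 510 groups of named-gene levels 11 did, or 2.16%. The chance rate of about 1 in 20 holds for 4 independent values. Each group here is 2 technical replicates in each of 2 experiments, so that rate is no yardstick for these counts. In replicate 1 of experiment 1 with guides, NUSAP1 was at 278 CPM (others 316 to 323.3), CKAP2 at 233.6 (291.3 to 302.9), IGFBP5 at 2.72 (3.34 to 3.42) and GPNMB at 83.9 (71.5 to 73.4). In replicate 2 of experiment 2 with guides, HSPA4L was at 230.7 (215.9 to 216.8). Without plasmid, ANKRD1 was at 3.71 (4.37 to 4.50) and SDHA at 495.2 (434.2 to 443.5) in replicate 2 of experiment 1, and ACAT2 at 103.9 (93.4 to 94.96) in replicate 1 of experiment 2. With dCas9-VP160 alone, LDHA was at 1542 (1458 to 1468) in replicate 2 of experiment 1, DKC1 at 155.7 (161 to 161.5) in replicate 2 of experiment 2 and CR1L at 0.437 (0.877 to 0.967) in replicate 1 of experiment 2.

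The response to dCas9-VP160 alone differed between the experiments for 2 genes by the edgeR interaction test. RCC2, a regulator of chromosome condensation (chromosome 1, 17406760 to 17439724), was lower by log2 fold changes of -0.72 and -0.21 in experiments 1 and 2, a difference of 0.51 (adjusted p = 0.0348). RPL37A, a ribosomal protein gene whose reads can be shared with related genes and pseudogenes (chromosome 2, 216498189 to 216579180), had 0.22 and -0.29, a difference of -0.50 (adjusted p = 0.0348). DESeq2 called 0 genes in this test, edgeR had 926 at an unadjusted p under 0.05, and the spread is that of technical replicates.

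Spike-in sequences, which no comparison uses, made up 0.719% and 0.404% of counts in replicates 1 and 2 of experiment 1 without plasmid. The other libraries held at most 0.00818%. With both of these libraries left out, all 38 called gene lists and all 263 results of named genes kept their direction. Part of them concern adding guides, a comparison that does not contain these libraries, so those could hardly change. The fit leaves 1 experiment without plasmid, so its calls are not given.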

How the results depend on the processing

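Chosen after the results were seen were the alternatives with replicate 1 or replicate 2 libraries only, without the experiment 1 controls, without the mitochondrial genes, and with an estimated correlation on 12 libraries. CD34 kept its direction over 29 alternatives, at 6.71 to 6.86 with guides against dCas9-VP160 alone (largest adjusted p 3.85e-08), 5.29 to 6.02 with guides against no plasmid (7.29e-08) and -1.42 to -0.83 with dCas9-VP160 alone (6.62e-05 to 0.109). It lost its call once, at -0.83 from the replicate 1 libraries only, with fewer libraries. Higher and lower genes on adding guides (817 and 670) were 248 and 174 from experiment 1 alone and 171 and 145 from experiment 2 alone, with fewer libraries compared and the spread of technical replicates, and 456 and 336 from replicate 1 only and 255 and 162 from replicate 2 only, with fewer libraries. They were 390 and 244 at an adjusted p under 0.01, and 19 and 57 with an absolute log2 fold change of at least 1, which are stricter. They were 1247 and 1077 with limma-voom (correlation within units -0.17), 270 and 90 with DESeq2 and 1 and 0 with edgeR without the experiment term (1465 at an unadjusted p under 0.05). Without that term the differences between experiments, which correlated at 0.604 to 0.627 between groups, enter the spread. How far this accounts for the lower counts was not tested, nor was the cause for limma-voom and DESeq2. With 1 library left out the counts on adding guides ran from 420 and 303 (without replicate 2 of experiment 2 without plasmid) to 1030 and 840 (without replicate 1 of it). They were 501 and 400 without replicate 1 of experiment 1 with guides. With dCas9-VP160 alone against no plasmid the counts were 3036 and 2528 without the experiment term, 3417 and 2757 with DESeq2, and 868 and 605 with the fold threshold. For guides against no plasmid they were 3229 and 2869 without that term, 2929 lower with DESeq2, and 806 and 761 with the fold threshold. For these 2 method changes the cause was not tested. Leaving out 1 library gave 4637 to 5208 and 4122 to 4853, and 4770 to 5362 and 4374 to 5038. DESeq2 size factors in edgeR made 61.3% of guide calls higher, against 54.9%. The median shift of log2 fold changes over all genes was at most 0.0119, for guides against no plasmid with only the 2 groups compared. With DESeq2 size factors it was at most 0.0105. Genes whose response differed between experiments numbered 6 without a filter and 0 with DESeq2 for dCas9-VP160 alone (2 with edgeR), and 5 without a filter and 3 with DESeq2 size factors for guides against no plasmid (0 with edgeR). The cause was not tested.

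Signs reversed for 5 genes on adding guides, of which FN1 alone is called (0.0278 from replicate 2 only), and the cause was not tested. PFKFB2 was at 0.0507 from experiment 2 alone, 0.0114 from replicate 2 only, and -0.16 (without replicate 1 of experiment 2 with guides) to 0.0095 (without replicate 1 of experiment 1 with dCas9-VP160 alone). YOD1 was at -0.0031 from experiment 2 alone, -0.0236 from replicate 1 only, and -0.0623 to 0.10 without replicate 1 or 2 of experiment 2 with guides, and also negative without replicate 2 of experiment 1 (-0.0173) or 2 (-0.0396) with dCas9-VP160 alone. FCMR was at -0.27 from experiment 1 alone, and MIR29B2CHG at 0.69 from experiment 2 alone, 0.50 from replicate 2 only, and -0.28 (without replicate 2 of experiment 2 with guides) to 0.35 (without replicate 1 of experiment 1 with dCas9-VP160 alone), and 0.21 without replicate 1 of experiment 1 with guides. Of 38 called lists none reversed, and 1 stayed called with an estimated correlation, 23 with it on 12 libraries, 33 with fry, 36 without the experiment term or a filter, and 35 to 38 otherwise. The 5 lists that fry did not call all concern adding guides. They were the p53 targets (fry adjusted p = 0.0963), ribosomal protein genes (0.233), TGF-beta and YAP targets (0.0959), immediate early genes (0.153) and mitochondrially encoded genes (0.0963). A replicate block on 12 libraries gave 729 and 613 genes on adding guides, of which 702 and 586 are among the 817 and 670, and kept all 38 lists and 252 of 261 results of named genes. The other 9, IFIT2 and FN1 among them, concern adding guides. Over the 3 comparisons, results of named genes also lost their call in 84 cases without the experiment term and 29 with DESeq2. They did so in 42 cases from experiment 1 alone and 52 from experiment 2 alone. Differences between replicates correlated at 0.0899 to 0.108 between the 2 experiments of a group and at -0.178 to 0.0415 between groups, so the number does not pair libraries across groups. A unit that lost a library had 1 technical replicate, assumed to vary like the others. Depth leaves genes with 0 counts undetermined below 0.251 to 0.444 CPM.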

Other observations

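Chosen only after the results were seen were the gene families below, the tests of a shared replicate batch, of fewer transfected cells and of library depth, those of a stronger overall response and of the replicate 2 libraries, the test of noncoding transcripts in general, and the limit to splits that keep technical replicates together. Other divisions of the 8 libraries of a comparison into 4 and 4 were fitted by edgeR. Of the 35 splits 3 keep the technical replicates of a unit together, which are too few for a share under 0.05. For dCas9-VP160 alone against no plasmid 1 of these 3 splits, the real one, gave as many genes as its 9626, and the highest other gave 2. For guides against no plasmid it was likewise 1 of 3 (9872, highest other 2). For guides against dCas9-VP160 alone 2 of 3 splits gave as many as the real 1512. The other of these, with 1786 genes, parts the 2 experiments, a batch of cells, and was fitted without an experiment term, whereas the real split had one. With the technical replicates summed and the experiment as a block 1487 genes were called.

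Some gene families were picked by their values, so counts and medians are given for them without a test of the family. Of 20 cytosolic tRNA synthetase genes, 6 of them in the integrated stress response list, 18 were higher and 1 lower with dCas9-VP160 alone than without plasmid (median 0.60). Outside that list YARS1 (1.18) and TARS1 (0.85) rose, QARS1 fell (-0.55), and HARS1 was not called (0.03). Of 17 mitochondrial tRNA synthetase genes 4 were higher and 5 lower. When guides were added, 7 cytosolic tRNA synthetase genes were higher and VARS1 was lower (-0.31). Of 58 genes of transport between the endoplasmic reticulum and the Golgi, 2 of them in the unfolded protein response list, 30 were then higher and COPZ2 (-1.14) was lower (median 0.16). The translocon gene SEC61A1 (0.33) and the coat protein gene COPA (0.30), both outside that list, rose. Of 14 serine/arginine-rich splicing factor genes 0 were higher and 8 lower by edgeR when guides were added, with SRSF2 at -0.31 and SRSF7 at -0.26 (median -0.17). Of 8 MAGE family genes, whose reads can be shared with their paralogs, 6 were higher and 0 lower with guides (median 0.55), MAGEB18 (0.76) and MAGEC2 (0.61) among them. With dCas9-VP160 alone against no plasmid 5 of the 8 were higher and MAGED2 (-0.70), MAGED1 (-0.31) and MAGEE1 (-1.15) lower.

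In the cells with guides, mitochondrially encoded transcripts were higher in replicate 2 than in replicate 1 for 15 of 15 genes (median log2 ratio 0.58, range 0.34 to 1.45), among 75 genes higher and 17 lower, with IFIT2 (-1.25) and H1-4 (-1.03) lower. A library batch shared by all replicate 2 libraries is argued against by the medians of the other groups, 0.0588 with dCas9-VP160 alone and -0.14 without plasmid. Replicates also differed in those groups. Without plasmid 7 genes were higher and 31 lower in replicate 2, with 5 of 15 mitochondrial genes lower and 0 higher. MT-ATP8 (-0.79) and MIF (-0.71), named after their values were seen, fell there but rose with guides (1.45 and 0.58). With dCas9-VP160 alone 18 were higher and 23 lower. Fewer transfected cells would move the 10054 nuclear genes called with dCas9-VP160 alone by the same share as the mitochondrial genes, but their slope on that contrast was -0.0343 (-0.0279 and -0.0408 in experiments 1 and 2), against -0.815 for the mitochondrial genes. Library depth is argued against by the ratio of replicate 2 to replicate 1, which was 1.07 in experiment 1 and 0.786 in experiment 2. No biological explanation was tested, as the labels call these technical replicates. A difference in the handling of single libraries, with guides or in the other groups, stays open.

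Unfolded protein response genes were higher with guides than with dCas9-VP160 alone (median 0.17), though the list was not called with an estimated correlation (camera adjusted p = 0.164). A generally stronger response to transfection stays open. Of the other lists called higher with dCas9-VP160 alone and called again on adding guides, 2 were then lower. NF-kB targets had a median of -0.28 (0 higher and 9 lower by edgeR) and immediate early genes one of -0.10 (1 and 5). Integrated stress response genes (11 and 2), p53 targets (9 and 1) and S phase genes (18 and 1) were higher. With an estimated correlation none of these lists was called on adding guides (adjusted p = 0.164 to 0.463). Both comparisons share the libraries with dCas9-VP160 alone. GC content or gene length bias is argued against by a median of 0.18 after a trend on both, which explained 1.07% of the variance, was taken out. The replicate 2 libraries with guides are argued against by a median of 0.22 from the replicate 1 libraries only. Load of the CD34 glycoprotein on the endoplasmic reticulum may explain the rise, as a hypothesis, but the design varies CD34 and the guide plasmids together, so neither these nor the amount of dCas9-VP160 plasmid was tested, and guides for a target that is not secreted or membrane-bound would be needed to part them.

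Small nucleolar RNA host genes were higher with dCas9-VP160 alone than without plasmid for 18 of 29, and SNHG4 was lower (median 0.44). GC content or gene length bias is argued against by a median of 0.45 after that trend was taken out. A rise of noncoding transcripts in general is argued against by a median of -0.0534 over 3293 other long noncoding and antisense genes, 477 higher and 560 lower. Slower nonsense-mediated decay, which degrades many of these host transcripts, could raise them, and the genes of 6 decay factors had a median of 0.17, with SMG1 (0.43), UPF3B (0.44) and SMG6 (0.18) called higher. This value lies between the bounds set for and against that explanation, so it stays open.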
